A study of Mus musculus with 18 samples.

How the data were processed

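RNA sequencing was done on livers of male C57BL/6J mice, a common inbred laboratory strain, in 8 Young and 10 Old animals. Per the labels, the Young mice were 6.18 and the Old mice 19.76 months old, whereas the design text gives 6 and 20 months and the growth protocol 21 months for the Old mice. Every liver was taken at the end of a hyperinsulinemic-euglycemic clamp, in which insulin is infused and blood glucose is held level by a glucose infusion, so that no liver without insulin infusion was compared. Per the labels' protocols, ribosomal RNA was depleted and RNA was extracted with either of 2 kits: AllPrep for 3 Young and 5 Old mice, and RNeasy for 5 Young and 5 Old mice. Groups and replicate numbers came from the labels. No replicate number occurs in both groups, so no pairing of mice was possible.

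The deposited table holds TPM, reads divided by gene length and scaled to 1 total per library, for 18946 genes in 18 libraries, and each library sums to 1000000 over the listed genes. STAR 2.7.9a, Subread and featureCounts are named per the submitters' processing notes, together with the builds GRCm39 and mm10, without a role for each. The gene lengths, the annotation and the strand setting behind the deposited TPM values are not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense genes are uncertain, and no coordinates are given. An Ensembl identifier was missing in the table for 3196 genes, and symbols were used as the table gives them. All 18 columns were assigned to mice, and the table listed none of the protein-coding genes of mitochondrial DNA.

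TPM carries no depth of its own, but the values of a gene in different libraries stood in ratios of whole numbers. Whole read numbers were found for 18946 of 18946 genes, with a largest distance from a whole number of 2e-08. In simulated tables of 1472 and 18917 genes the procedure returned 100% of the genes. The recovered reads over the listed genes came to 85790735 to 127487820 per library. A count of 0 in a library allows up to 3 reads, a floor that covers counting error only. To look for a library listed more than once, the reads of all 73 pairs of libraries of the same age were compared: the lowest chi-square per degree of freedom was 43.4 among Young and 83.9 among Old pairs, so that no pair agreed within sampling noise.

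Count tests had been planned, before the data were examined, on the assumption of a table of counts. As the deposited unit was TPM, age was tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 0.5), with a variance trend and with age and kit as terms. The TPM values were first scaled by a trimmed mean of log ratios, with 30% of log ratios and 5% of mean levels trimmed at each end. Genes with at least 0.5 TPM in at least 8 libraries were tested, which left 13895. These settings were chosen after the files had been looked at, including a first view of how the libraries group, and before any gene was called. A fold change is on the scale of log2(TPM + 0.5) and understates changes of low genes. Benjamini-Hochberg adjusted p-values under 0.05 were counted as calls. In simulated libraries of 13704 genes, with 8 and 10 libraries, 34% of the genes changed 1.25-fold were called, 78% of those changed 1.5-fold, 92% of those changed 2-fold and 96% of those changed 4-fold, with 8 false calls among 158. In the simulation genes varied independently, with no kit effect and no library that stands apart, so these rates need not hold for the real libraries.

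Genes to be named were fixed before the data were examined: the 8 largest rises and 8 largest falls among called genes with a mean log2 level of at least 2 and a regular symbol, up to 4 members with the smallest p of called lists for at most 14 lists, and 9 genes of insulin action whatever their result. In total 73 genes met this rule, and 1 of them is not reported here. Immunoglobulin segments and the Mup family were treated only as groups. The 39 gene lists were fixed at the same time and 37 had the 4 tested members needed. They were tested with camera at a preset inter-gene correlation of 0.01, and with an estimated correlation and fry as alternatives. The slope of each gene on the percent suppression of glucose production was tested in limma with age and kit as terms.

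Traits of the mice came from the labels. The 18 traits were compared with two-sided exact permutation tests of the difference in means, adjusted over the 18. Where no unit is stated in the labels, ratios of means are given. Of 12 correlations of a gene with a trait within an age, those in Young mice have exact permutation p-values and those in Old mice p-values from 100000 permutations. Calculations outside limma used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

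Alternatives covered the kit term, each kit alone, the scaling, the filter, the pseudocount, a minimum fold of 1.2, body weight as a term, and each library left out in turn. Chosen after the data had been seen were, for single genes, the fit with no composition factor, and further pseudocounts of 0.1 and 1, limma-voom on the recovered reads, library weights, a robust prior, the gas exchange traits without 3 Old mice whose labelled energy expenditure differed from their gas values, and the analyses without Old replicate 14 outside the planned series of left-out libraries.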

Results

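Liver RNA of 8 Young and 10 Old male mice was sequenced after an insulin clamp, and the labels give traits of these mice. The series asks how the liver of old mice differs from that of young mice under insulin. Recovered reads over the listed genes came to 106638287 ± 14397482 per library in Young (SD, n = 8) and 106948396 ± 11475262 in Old (SD, n = 10). The 2 means did not differ in an exact permutation test (p = 0.959). Each mouse is a separate animal per the labels.

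Old mice needed far less glucose during the clamp and their livers kept releasing it. Insulin suppressed glucose production by 80.8% ± 7.74 in Young mice (SD, n = 8) and by 43.1% ± 15.1 in Old mice (SD, n = 10), with an exact permutation p of 9.14e-05 and an adjusted p of 0.000329. The glucose infusion rate in Old mice was 0.388 times that in Young mice, with an exact permutation p of 2.29e-05, the smallest that the 43758 regroupings can give. Clamp glucose production was 3.31 times as high in Old mice, whereas clamp insulin did not differ (ratio 1.03, exact permutation p = 0.702). Liver glycogen was lower in Old mice at 0.592 times the Young mean (adjusted exact permutation p = 0.000514), as were liver citrate synthase flux at 0.761 times (0.000411) and pyruvate dehydrogenase flux at 0.525 times (0.00202). Glycerol suppression, a measure of how insulin restrains fat breakdown, was 60.3% ± 11.2 in Young (SD, n = 8) and 29.3% ± 13.8 in Old (SD, n = 10), with an adjusted exact permutation p of 0.000329.

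**Figure D1:**
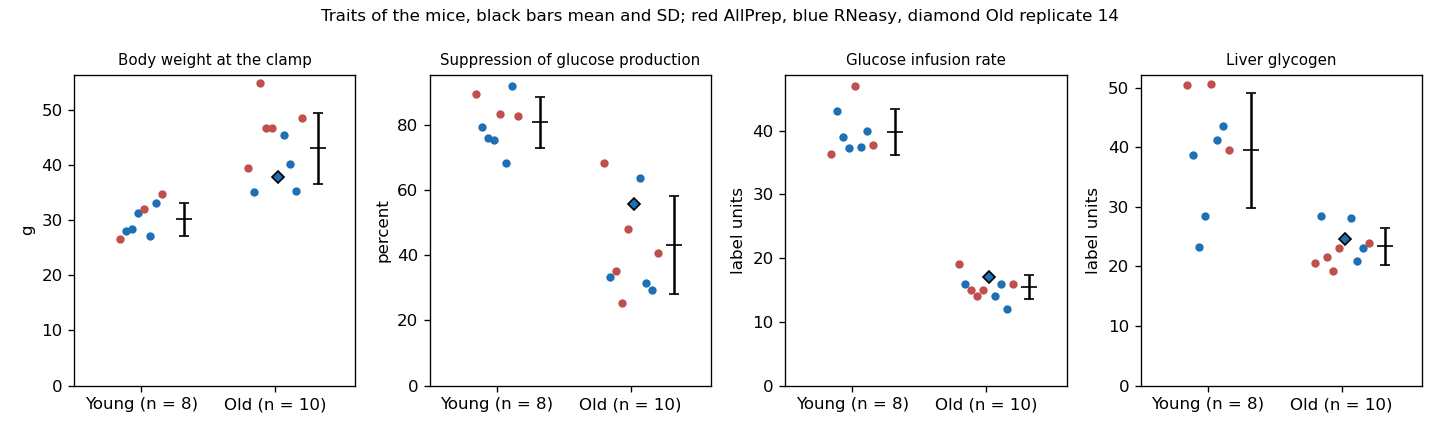
Body weight at the clamp in g, suppression of glucose production in percent, and glucose infusion rate and liver glycogen in the units of the labels, which are not stated; each point is 1 mouse, coloured by extraction kit, and black bars are mean and SD. The glucose infusion rate of the 10 Old mice lies below that of the 8 Young mice, with no overlap.

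Old mice weighed 43.1 ± 6.45 g (SD, n = 10) and Young mice 30.2 ± 3.02 g (SD, n = 8), with an adjusted exact permutation p of 0.000411. Body fat, measured in 7 mice of each age, was 26.8% ± 7.20 in Old and 11.4% ± 4.56 in Young (SD, n = 7 each, adjusted exact permutation p = 0.0035). It refers to the labelled weight on leaving the cage, which could differ widely from the clamp weight under the same label. Old replicate 6 weighed 48.6 g on leaving the cage and 35.1 g at the clamp, and Old replicate 9 weighed 34.2 and 46.7 g. Why these weights differ was not tested, and the cage traits may belong to another time than the clamp traits. Basal insulin was 1.91 times as high in Old mice (adjusted exact permutation p = 0.00185) and basal glucose production 1.13 times (0.0223). The Young mean of basal insulin includes Young replicate 3, listed as 0, and the ratio without that value was not computed. The pyruvate share of citrate was 0.685 times the Young mean (adjusted exact permutation p = 0.0418), a call that the exact rank-sum test does not make (adjusted p = 0.175). In each mouse, pyruvate dehydrogenase flux divided by citrate synthase flux nearly equalled this labelled share (8.63% against 8.64% in Young replicate 1). The share and the 2 fluxes are therefore not independent traits. Basal glycerol (adjusted exact permutation p = 0.0751), the respiratory exchange ratio (0.328) and oxygen use per lean mass (0.438) did not pass the threshold. Both gas exchange values depend on 3 of the 7 Old mice (replicates 6, 14 and 15, and 0 Young mice), whose labelled energy expenditure differed by more than 2% from the value computed from their gas exchange. Without these 3 mice oxygen use was 0.799 times the Young mean (exact permutation p = 0.00303, the smallest that 330 regroupings can give, adjusted p = 0.0042, n = 7 and 4), and the respiratory exchange ratio turned from 0.960 to 1.02 times (adjusted exact permutation p = 0.484). The 3 mice had oxygen use of 3726 to 4898 in label units, and the 4 Old mice kept 2636 to 3169, so the exclusion itself lowers the Old mean. All 3 belonged to the RNeasy set and all 4 kept to the AllPrep set.

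In the livers, 339 genes were higher and 343 lower in Old than in Young mice among 13895 tested with limma. Cyp2b9, a cytochrome P450 that is higher in female than in male mouse liver, rose most: from 0.273 ± 0.293 scaled TPM in Young (SD, n = 8) to 64.1 ± 81.8 in Old (SD, n = 10), a log2 fold of 4.72 ± 0.85 (SE, limma adjusted p = 0.00589; 0.0762 with limma-voom on recovered reads). Its Old mean was 42.5 without Old replicate 14, which had 257.6 scaled TPM, and the other RNeasy libraries of Old mice had 1.11 to 9.34. In RNeasy libraries alone its log2 fold was 3.61 and was not called (limma adjusted p = 0.363). Arrdc3, an arrestin domain protein that acts in receptor trafficking, rose by a log2 fold of 1.91 ± 0.24 (SE, limma adjusted p = 0.000894) and was above the Young median in 10 of 10 Old mice. Rgs16, a regulator of G protein signalling, rose by 3.38 ± 0.55 on the log2 scale (SE), although Old replicate 14 alone reached 336.1 scaled TPM and the other Old libraries 10.8 to 33.2. Other large rises were Cidea, a lipid droplet protein (log2 fold 2.03), Serpinb1a, a protease inhibitor (1.85), Sult2a7, a sulfotransferase (1.84), Cxcl1, a chemokine for neutrophils (1.68), and Cyp2a22, a cytochrome P450 (1.43).

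The largest fall was in Ppp1r3g, a subunit that directs protein phosphatase 1 to glycogen, with a log2 fold of -2.56 ± 0.54 (SE, limma adjusted p = 0.0141), from 17.2 ± 14.4 scaled TPM in Young (SD, n = 8) to 2.31 ± 2.99 in Old (SD, n = 10; mean 1.51 without Old replicate 16). Ugt2b38 (log2 fold -2.52), Selenbp2 (-2.23) and Cyp4a12b (-2.02), genes higher in male liver, fell as well. Gadd45g (-2.22), Nr4a1 (-1.81) and Myc (-1.78), genes with fast transcriptional responses, and Cd163 (-1.72), a scavenger receptor of macrophages, completed the 8 largest falls. Ppp1r3g was below the Young median in 10 of 10 Old mice, and so were Ugt2b38, Gadd45g, Nr4a1, Myc and Cd163.

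**Figure D2:**
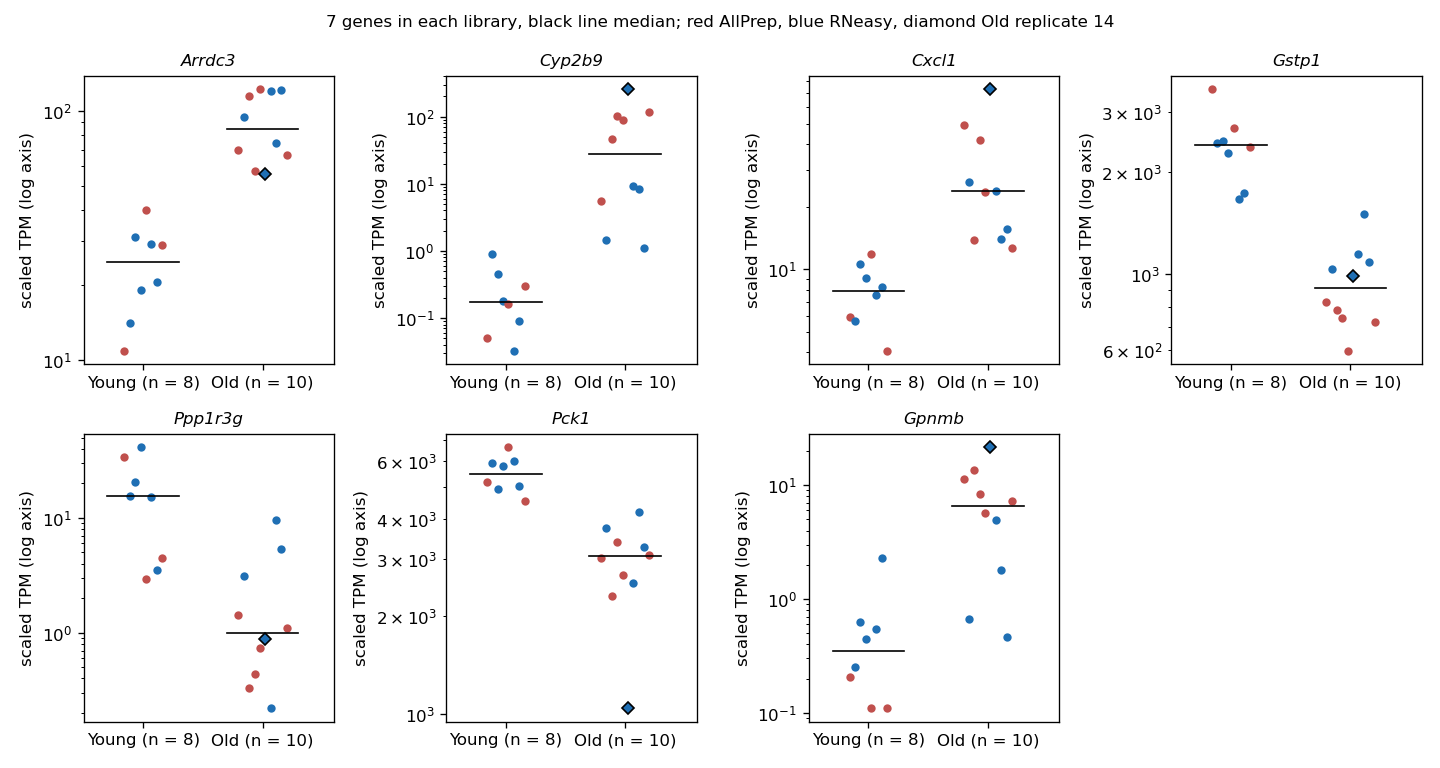
Scaled TPM on a log axis for 7 genes in the 8 Young and 10 Old livers; each point is 1 library, red for AllPrep, blue for RNeasy and a diamond for Old replicate 14, and black lines are medians. Gstp1 and Arrdc3 separate the ages with no overlap, with log2 folds of -1.33 and 1.91. Pck1, Cxcl1 and Cyp2b9 also separate the ages, and Ppp1r3g and Gpnmb overlap.

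Among the genes of insulin action fixed in advance, Pck1, which encodes the enzyme that commits carbon to glucose synthesis, was lower in Old mice, at 2925 ± 869 scaled TPM (SD, n = 10) against 5509 ± 703 in Young (SD, n = 8). Its log2 fold was -0.99 ± 0.21 (SE, limma adjusted p = 0.0137), and Old replicate 14 was lowest at 1039 scaled TPM. These 7 did not pass: G6pc, the last step of glucose release (-0.49, limma adjusted p = 0.0719), Igfbp1 (-1.15, 0.226), Irs2 (-0.48, 0.12), Srebf1 (0.22, 0.638), Fasn (0.84, 0.264), Pdk4 (0.88, 0.135) and Insr, the insulin receptor (0.10, 0.616). Without Old replicate 14 the log2 folds of Fasn and Srebf1 were 0.42 and 0.07, and in RNeasy libraries alone that of Insr was -0.02.

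The gene counts moved with several choices. With library weights 704 genes were higher and 697 lower, and against a fold of 1.2 there were 19 and 7. With body weight as a further term, 3 genes, the predicted genes Gm52520, Gm25835 and Gm10069, named after their values were seen, were higher and 0 lower (limma, 1730 genes at an unadjusted p under 0.05), and weight and age go together in these mice. Within the AllPrep libraries 103 genes were higher and 59 lower, and within the RNeasy libraries 9 and 7, or 31 and 27 without Old replicate 14. A test of the kit by age interaction called 0 genes in limma (587 at an unadjusted p under 0.05) with all libraries and 3 (1168) without Old replicate 14. These were Ugt2b38, Cd163 and Ces4a, the last named after its values were seen, whose log2 folds were lower in AllPrep than in RNeasy libraries (differences of -3.23, -2.41 and -1.23). Of the named genes, 29 calls were lost in RNeasy libraries alone. There the log2 folds of Ugt2b38 (-1.45), Selenbp2 (-1.27), Cd163 (-0.97), Gstp1 (-0.87), Cspg5 (-0.64), Ehhadh (-0.47) and Stat2 (0.22) were over 1.5 times smaller than with both kits. The same held for the macrophage genes Gpnmb (1.43) and Ms4a7 (0.58). In AllPrep libraries alone 16 calls were lost. With no composition factor the counts were 341 and 188, so that 64.5% of the calls were higher in Old, against 49.7%. Leaving out 1 library moved a count by over 1.5 times for Young replicates 1 (180 higher, 195 lower), 2 (198, 188), 4 (228 lower), 10 (176, 184), 11 (220, 209) and 12 (219, 216) and for Old replicates 7 (219, 221), 9 (208, 213) and 15 (213, 205). Without Old replicate 14 the counts were 500 and 464, and 622 genes were called with the same sign with and without it.

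Of the 39 gene lists, the male-biased hepatic genes moved most. Of 18 tested members 0 rose and 9 fell, with a median log2 fold of -1.30, or 16 lower when adjusted over the list alone. Gstp1, a glutathione transferase, fell from 2394 ± 577 to 944 ± 266 scaled TPM (SD, n = 8 and 10; log2 fold -1.33 ± 0.17 SE, limma adjusted p = 0.000894), and Cspg5 had a log2 fold of -1.03. The camera test called the list lower at the preset correlation of 0.01 (adjusted p = 1.2e-11). It did not with the estimated correlation of 0.656 (adjusted p = 0.69), and fry gave an adjusted p of 0.0571. Without Old replicate 14, which stands apart from the other libraries, 12 members fell, the median was -0.93 and fry gave an adjusted p of 0.00795. The mean of the list fell by 1.74 on the log2 scale within AllPrep (exact permutation p = 0.0179, n = 3 and 5) and by 1.00 within RNeasy (exact permutation p = 0.0159, n = 5 each), or by 0.43 without Old replicate 14 (exact permutation p = 0.0397, n = 5 and 4).

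Lipid-associated macrophage markers, genes of macrophages that take up lipid, had 5 of 16 tested members higher and 0 lower, or 7 when adjusted over the list alone. Gpnmb, a membrane glycoprotein (log2 fold 2.47), Mmp12, a macrophage elastase (1.85), Trem2, a lipid receptor (1.24), and Ms4a7 (0.92) rose, although Gpnmb did not pass with limma-voom (adjusted p = 0.0605). In RNeasy libraries alone these 4 were not called, at 1.43 for Gpnmb (limma adjusted p = 0.618), 1.32 for Mmp12 (0.541), 0.96 for Trem2 (0.512) and 0.58 for Ms4a7 (0.621). In AllPrep libraries alone Gpnmb stood at 3.81. The median log2 fold of the list was 0.74, and 0.44 without Old replicate 14. B and plasma cell markers had 3 of 15 members higher and 0 lower, or 9 higher and 1 lower when adjusted over the list alone, with Jchain, the joining chain of antibodies, at a log2 fold of 1.44. Pou2af1 (0.56), Mzb1 (0.51) and Derl3 (-0.89) did not pass. The camera calls of both lists (adjusted p = 1.44e-05 each) were lost with an estimated correlation (adjusted p = 0.69 each). General markers of Kupffer cells and macrophages had 0 of 20 higher and 1 lower (Cd163), or 4 higher and 1 lower when adjusted over the list alone, with a positive log2 fold in 17 and a median of 0.28. The camera test called this list higher (adjusted p = 0.0199), but not with an estimated correlation (0.69) or without Old replicate 14 (adjusted p = 0.145, median 0.16). T and NK cell markers had 0 of 17 called and hepatocyte markers 0 of 15, and 0 as well when adjusted over the list alone.

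Immune signalling lists lay on the side of higher expression with few members called. Interferon response genes had 1 of 34 members higher, Stat2 (log2 fold 0.44), also the 1 member called when adjusted over the list alone, while Cxcl10 (0.74), Gbp2 (0.55) and Cxcl9 (0.87) did not pass. Stat2 was not called without the kit term (limma adjusted p = 0.125). MHC class II genes had 0 of 9 called, and 7 higher when adjusted over the list alone, with Cd74 at 0.69, H2-Eb1 at 0.74, Ciita at 0.51 and H2-DMa at 0.41. In RNeasy libraries alone these genes stood at 0.26, 0.23, 0.25 and 0.18, and in AllPrep libraries alone at 1.24, 1.42, 0.85 and 0.71. They were called in neither kit, and the shift was larger in AllPrep libraries. Genes of p53, senescence and secretion had 2 of 18 higher, Cxcl1 and the monocyte chemokine Ccl2 (1.26), or 4 when adjusted over the list alone, whereas Ccng1 (0.25) and Gdf15 (1.02) did not pass. The camera calls of these 3 lists were lost with an estimated correlation (adjusted p = 0.69).

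Metabolic lists showed small shifts. Insulin-repressed genes of glucose production had 0 of 15 higher and 1 lower, or 6 lower and 1 higher when adjusted over the list alone, with Pck1 called and Tat (-0.88) and Ppargc1a (-0.40) not. Tat passed without Old replicate 14 (-0.61, limma adjusted p = 0.00262). Insulin-induced genes of lipogenesis and glycolysis had 1 of 19 higher and 0 lower, or 3 and 1 when adjusted over the list alone and 2 and 0 without Old replicate 14. Their median log2 fold was 0.38, and Gpam (0.36), Fads1 (0.38) and Me1 (-0.41) did not pass. Gpam passed with no composition factor (limma adjusted p = 0.0489) and without Old replicate 14 (0.02). Nuclear-encoded oxidative phosphorylation genes had 0 of 42 called, 0 when adjusted over the list alone, and a negative log2 fold in 39, with a median of -0.12 and Ndufv1 (-0.24), Cyc1 (-0.23), Uqcrfs1 (-0.19) and Uqcrc1 (-0.20) at the smallest p. Pyruvate and citric acid cycle enzymes had 0 of 24 called, or 2 lower when adjusted over the list alone, with Pdhx at -0.26, Fh1 at -0.48, Idh3a at -0.35 and Suclg2 at 0.19. Fatty acid oxidation genes had 1 of 24 lower, Ehhadh (-0.72), and 0 when adjusted over the list alone, and Acadvl (-0.21), Cyp4a14 (-0.86) and Acaa1b (-0.30) did not pass. Ehhadh was not called with median-of-ratios scaling (limma adjusted p = 0.0521), no composition factor (0.0627) or no kit term (0.053), and Cyp4a14 stood at -0.54 without Old replicate 14. Each of these 5 lists was called by camera and lost with an estimated correlation (adjusted p = 0.69).

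Pericentral hepatocyte genes, which mark the zone around the central vein, had 1 of 19 lower, Notum (-0.48), or 2 when adjusted over the list alone, while Cyp1a2 (-0.78), Oat (-1.01) and Gulo (-0.31) did not pass. Without Old replicate 14 Oat (-0.66, limma adjusted p = 0.0218) and Cyp1a2 (-0.58, 0.0464) passed, and with no composition factor Notum did not (0.0527). The unfolded protein list had 1 of 22 higher, the stress factor Ddit3 (0.53), or 1 higher and 1 lower when adjusted over the list alone, although its median was -0.28 and Dnajc3 (-0.28), Hyou1 (-0.49) and Calr (-0.45) did not pass. Ddit3 was not called without the kit term (limma adjusted p = 0.222) and stood at 0.25 in AllPrep libraries alone, and Dnajc3 passed with median-of-ratios scaling (0.0491). Immediate early genes had 1 of 17 higher, Klf6 (0.69), and 2 lower, Myc and Nr4a1, or 1 and 3 when adjusted over the list alone, and Jund (-0.30) did not pass. These camera calls were lost with an estimated correlation as well (adjusted p = 0.69). The other lists called by camera, among them cholesterol synthesis (0 of 25 members called), stellate cell markers (0 of 16), fibrosis and extracellular matrix (0 of 26) and xenobiotic metabolism (1 of 23, lower), were lost too (adjusted p = 0.69 to 0.708 with an estimated correlation). In all, camera called 10 lists higher and 9 lower. Of these 0 remained with an estimated correlation (1 list at an unadjusted p under 0.05) and fry called 0 (8 at an unadjusted p under 0.05) with all libraries and 3 without Old replicate 14.

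**Figure D3:**
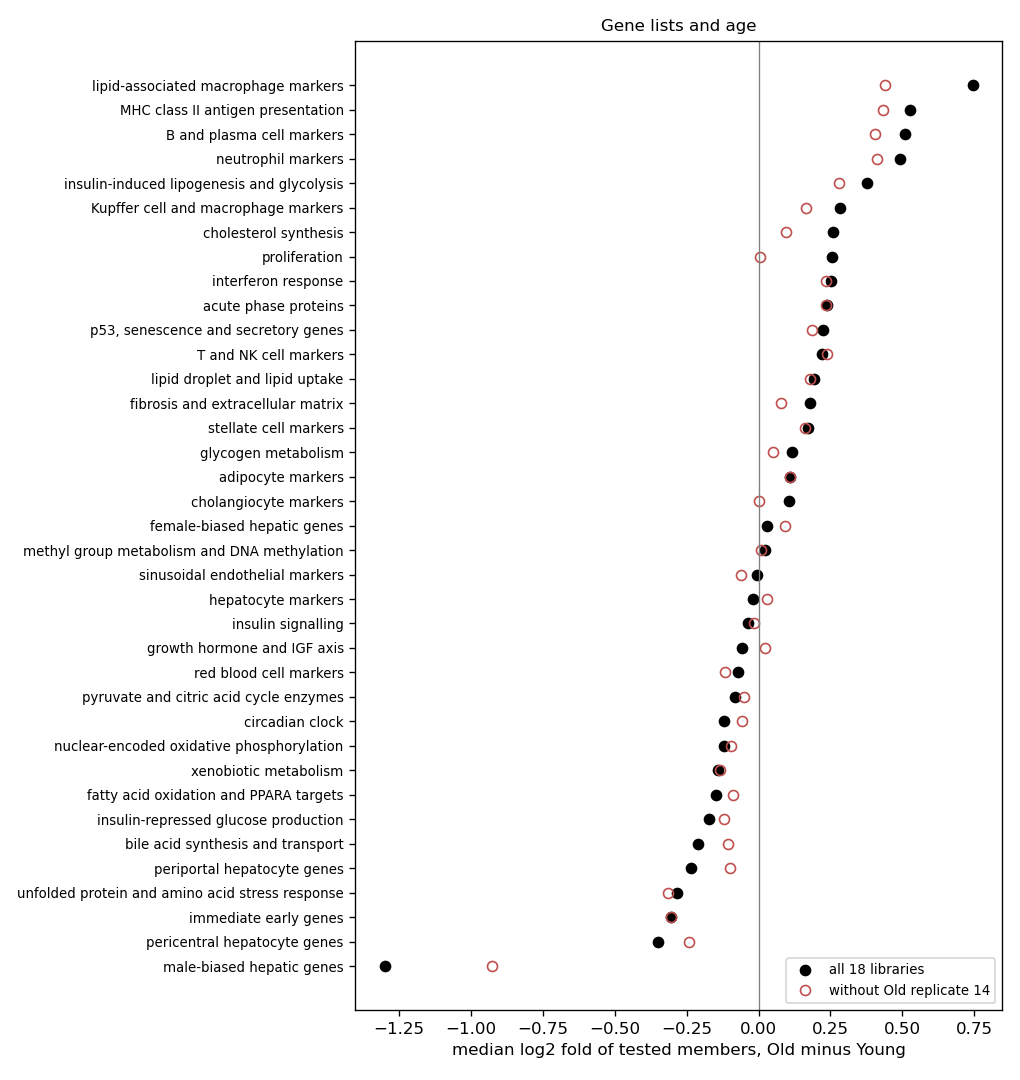
Median log2 fold, Old minus Young, over the tested members of each of 37 gene lists; filled points are all 18 libraries and open points leave out Old replicate 14. Male-biased hepatic genes lie lowest, at -1.30 and -0.93, and lipid-associated macrophage markers highest, at 0.74 and 0.44.

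Whether any gene followed the suppression of glucose production within an age was asked next. Steap2, a metalloreductase, had the smallest p, with a slope of -0.25 ± 0.04 log2 per 10 percentage points (SE, limma adjusted p = 0.13). Ppm1l, a phosphatase, had a slope of -0.15 ± 0.03 and Lect2, a protein secreted by hepatocytes, of 0.17 ± 0.04 (SE, limma adjusted p = 0.545 each). No gene passed: 0 rose and 0 fell in limma, with 1267 at an unadjusted p under 0.05. Without age in the model 16 genes rose and 27 fell with suppression, which differs between the ages.

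None of the 10 relations of a gene with a trait within an age that are reported passed adjustment over the family of 12. Pck1 and clamp glucose production in Old mice had r = 0.38 (permutation p = 0.29, adjusted 0.765, n = 10) and rho = 0.59 (permutation p = 0.0799), and r = 0.70 without the 2 mice farthest from the median. With Old replicate 14 left out, r was 0.45 (permutation p = 0.224, n = 9), and also 0.45 without the 2 farthest mice. The value of 0.70 thus depends on Old replicate 14. Pdk4, an inhibitor of pyruvate dehydrogenase, and the flux through that enzyme in Young mice had r = -0.58 (exact permutation p = 0.13, adjusted 0.765, n = 8) and rho = -0.48 (exact permutation p = 0.243), and r = -0.05 without the 2 mice farthest from the median, so that the value rests on those mice. For the other 8 relations the adjusted permutation p lay between 0.765 and 0.827.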

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

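The tests of Old replicate 14 named here were written after that library had been seen to stand apart, though before the genes they measure were looked at. In 184 groups of values, 17 had 1 sample far from the others, where chance gives about 9.2, and 9 of the 17 concern Old replicate 14.

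Old replicate 14 had 336.1 scaled TPM of Rgs16, 169.6 of Gpam, 20.9 of Klf6 and 500.4 of Fasn, each above the other 9 Old libraries. It had 1.38 scaled TPM of Cyp4a12b, 135.7 of Oat, 302.0 of Cyp4a14, 1039 of Pck1 and 183.2 of Tat, each below them. Over the tested genes, 75 were over 4-fold above and 19 over 4-fold below all of the other 17 libraries, whereas no other library had more than 2 above or 1 below. H19, a fetal growth RNA, stood at 263.6 TPM against at most 0.793 elsewhere, Afp, the fetal albumin, at 101.0 against 3.71, and Gpc3, a fetal liver proteoglycan, at 79.4 against 3.10.

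A candidate explanation for this library is tissue from a liver tumour: of 12 genes of a tumour list present in the table, 9 were highest in it. The share of all tested genes that were highest in this library was not computed, so this count does not single out tumour tissue. Gut RNA in the sample is also open by its test, since 3 of 5 gut genes present in the table (Vil1, Cdh17 and Slc5a1) were over 2 times the highest other library. However, 10 of the 15 listed genes could not be examined. Fabp2, abundant in gut and also made by liver, was not raised (267.0 against at most 306.9 TPM), and Muc2 was at 0.024 TPM. Epcam, an epithelial marker, was not raised either (0.368 against at most 1.69 TPM). On 964 genes called without this library, Old replicate 14 lay at 1.249, where 0 is the Young and 1 the other Old mean. That is outside the range of the Young libraries and argues against an otherwise ordinary young liver with the wrong label. Where a young liver altered as this one would lie is not known, so the test does not settle the label. No histology was analysed here, and the labelled age does not set this library apart, since the other 9 Old mice share it.

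Other single samples stood apart as follows. Young replicate 3 had 0.981 scaled TPM of Mzb1. Young replicate 12 had 1.42 of Mmp12 and 2.3 of Gpnmb. Young replicate 10 had 0.390 of Ccl2, and Young replicate 1 had 50.5 of Insr. Old replicate 18 had 17.0 of Stat2. Suppression of glycerol was -1.7% in Old replicate 7. Body fat was 11.1% in Old replicate 9, whose labelled weight was 34.2 g on leaving the cage and 46.7 g at the clamp.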

How the results depend on the processing

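Chosen after the data had been seen were, for single genes, the fit with no composition factor, and further the pseudocounts, limma-voom, library weights, the robust prior, the analyses without the 3 mice of doubtful gas exchange and the added analyses without Old replicate 14. The planned edgeR and DESeq2 tests and the surrogate variables of sva were not run, although whole reads had been recovered. No paired analysis was possible because the ages share no replicate number. Against 339 higher and 343 lower genes, the counts were 103 and 59 in AllPrep, 9 and 7 in RNeasy libraries, 31 and 27 in RNeasy without Old replicate 14, 19 and 7 against a fold of 1.2, 3 and 0 with body weight as a term, 704 and 697 with library weights, and 341 and 188 with no composition factor. Fewer samples in the kit sets and a stricter hypothesis in the fold test follow from their construction; for the others the cause was not tested. Leaving out 1 library gave 176 to 500 higher and 184 to 464 lower genes; no filter, at least 1 TPM, other pseudocounts, median-of-ratios scaling, no kit term, limma-voom and the robust prior stayed within 1.5 times. Against 10 lists higher and 9 lower, 4 were higher in RNeasy libraries, and 6 to 13 higher and 8 to 10 lower with 1 library left out (6 higher without Old replicate 14). There were 0 and 0 with fry, with an estimated correlation, or with the latter without Old replicate 14. Over the lists called, the estimated correlation ran from 0.158 (xenobiotic metabolism) to 0.835 (MHC class II), against the preset 0.01. By these estimates the camera p-values at the preset are too small, which accounts for the calls lost with an estimated correlation. For the other changes in list counts the cause was not tested. Genes related to suppression numbered 0 and 0 under each alternative except without age in the model (16 rising, 27 falling), and 0 with each library left out.

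Of 72 named genes, 70 kept their direction and side of the threshold with median-of-ratios scaling, 69 without the kit term (Stat2, Ddit3 and Ehhadh did not), 70 with limma-voom and 68 without Old replicate 14, where 4 passed that had not (Oat, Cyp1a2, Gpam and Tat). Without the 3 mice whose energy expenditure differs from their gas values, the adjusted exact permutation p of oxygen use passed at 0.0042 and the respiratory exchange ratio changed direction with an adjusted p of 0.484. Those 3 mice had the highest oxygen use of the Old mice, so the lower Old mean follows in part from leaving them out. With limma-voom Cyp2b9 and Gpnmb no longer passed. In RNeasy libraries alone 29 no longer passed, 20 of them with a log2 fold within 1.5 times, and Insr turned to -0.0202; in AllPrep libraries alone 16 no longer passed, 14 of them within 1.5 times, and Tat passed (-0.76, adjusted p = 0.0385). The uncalled correlations that changed sign were Cs with citrate synthase flux in Old (0.23) and Igfbp1 with suppression in Old (-0.19), both without Old replicate 14. The recovered depth was 85790735 reads or more in each library. The filter kept genes with few reads in 1 age, such as Cyp2b9 with 3 to 81 reads in Young libraries, whose log2 fold was 4.72, and 6.85 with limma-voom.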

Other observations

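Chosen after the result had been seen were the tests of Old replicate 14 alone on the male-biased list and on the RNeasy calls, the spread of the RNeasy libraries with Old replicate 14, and the comparison of body weight between kits, as was the use of left-out libraries to judge the ratio of age differences between kits; the other tests here were written before their results. Immunoglobulin segments, whose near-identical sequences make single members uncertain, had 21 of 54 tested members higher and 0 lower in Old mice, with a median log2 fold of 1.12, and 0.98 without Old replicate 14. The Mup family of pheromone-binding proteins, whose copies share reads, had 7 of 18 lower and 0 higher, with a median of -1.47, and -1.09 without Old replicate 14. Female-biased hepatic genes had 3 of 11 higher and 0 lower, with a median of 0.03 and a mean of 0.79. Lipid droplet genes had 2 of 17 higher and 2 lower.

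The fall of Nr4a1 and other fast-response genes led to a hypothesis that genes induced by cAMP, the second messenger of glucagon, were lower in Old mice as a group. Of 17 listed genes, chosen without those already seen, 15 were tested, and their mean was lower by a log2 difference of -0.45 (exact permutation p = 0.00101), and -0.41 without Old replicate 14. Of these, 5 fell, Nr4a2 (-1.49), Nr4a3 (-0.99), Cebpb (-0.90), Cebpd (-0.76) and Klf9 (-0.65), and 0 rose. The other tested members did not pass, among them Crem (-0.36), Pde4b (-0.39) and Crtc2 (-0.23). In all, 13 of the 15 log2 folds were negative, and Rgs2 (0.12) and Id1 (0.11) were positive. The list holds relatives of genes already seen to fall, such as Nr4a2 and Nr4a3 for Nr4a1, in the same mice, so the test is not independent of that observation. Weaker cAMP signalling stays a hypothesis, since several of the genes also respond to other stimuli, which was not tested.

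The lower male-biased genes of Old mice do not rest on Old replicate 14, since the list mean still differed without it (exact permutation p = 0.000329). The tables argue against the kit as the cause, because the list mean fell by 1.00 on the log2 scale in RNeasy and by 1.74 in AllPrep libraries, although without Old replicate 14 the RNeasy fall was -0.43 (exact permutation p = 0.0397). Body weight cannot be told apart from age: with weight as a term the difference was -1.24 with a 95% interval of -2.60 to 0.12, against -1.32 (-2.06 to -0.58) without it. An effect of age itself is an open explanation.

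Fewer genes were called in RNeasy (16) than in AllPrep libraries (162). Old replicate 14 is not the whole cause, since 58 were called without it. A larger spread does not account for those 58, since the median residual SD without this library was 0.79 times that of AllPrep. Over the 964 genes called without this library it was 0.84 times. For the 16 a larger spread stays open, since with this library the ratio was 1.05 over all tested genes and 1.20 over the 964. Without Old replicate 14 and over the 964 genes called without it, the age differences in RNeasy libraries were 0.747 times those in AllPrep, next to the bound of 0.75 set for the test and 0.695 to 0.809 with 1 further library left out, which leaves smaller differences open. At the clamp, Old mice of the AllPrep set weighed 47.3 ± 5.53 g and those of the RNeasy set 38.8 ± 4.28 g (SD, n = 5 each, exact permutation p = 0.0238). On leaving the cage, the Old mice with a value weighed 34.2 to 55.3 g in the AllPrep set and 43.9 to 48.6 g in the RNeasy set. The RNeasy range lies inside the AllPrep range, so whether heavier Old mice contribute to the larger AllPrep count stays open. The interaction test in limma called 0 genes with all libraries (587 at an unadjusted p under 0.05) and 3 without Old replicate 14 (1168), so a difference between kits in the age effect was shown without that library for Ugt2b38, Cd163 and Ces4a and with it for 0 genes.

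Chance is unlikely for the gene counts: of 100 splits of the 18 libraries, 1, the real one, gave 682 or more genes, and the highest other gave 13. Only 100 of 43758 possible regroupings were used, so chance is not excluded, and the splits do not tell age from body weight. Within AllPrep 1 of 56 splits reached 162, with 2 as the highest other, and within RNeasy 1 of 100 reached 16, with 1 as the highest other. The list counts could arise by chance: 11 of 100 splits gave 19 or more lists and the highest other gave 23.

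The kits themselves differed in 785 genes higher and 1755 lower in AllPrep. Of 337 tested genes with a recovered length under 200 nt, 212 were lower and 5 higher in AllPrep. In the labels, the pyruvate carboxylase value was within 2% of the product of suppression and a second labelled fraction in 16 of 18 mice; it was 38.6 against a product of 25.4 in Old replicate 17 and 1.71 against 34.3 in Old replicate 18. Energy expenditure differed by more than 2% from a value computed from the gas exchange in 3 of 14 mice, all of them Old (replicates 6, 14 and 15). Basal insulin was listed as 0 in Young replicate 3.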
